A study of Mus musculus with 9 samples.

How the data were processed

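RNA of the lateral nasal gland, a large secretory gland of the mouse nose, was measured on 9 1-colour Affymetrix arrays. Per the labels, 2 arrays came from wild-type 129/Sv mice, 4 from wild-type B6 mice and 3 from Cyp2g1-null mice, and each array held a pool of glands from 10 male mice aged 2 to 3 months. The null line is on a mixed background of both strains, so both served as controls. Each pool was treated as 1 replicate. The labels give no array batch or scan date, so no batch could be tested.

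The deposited values are signal intensities on a linear scale, computed by the authors with MAS5, per the submitters' processing notes; its version is not given in the sources used here. After 2% of the values were trimmed at each end, every array had a mean signal between 1499.9 and 1500.6, so the arrays had been scaled to a common level. Signals ran from 0.6 to 177173, and array medians from 518.5 to 550. No detection calls were used here, so the share of probe sets above background is unknown, and compression of the brightest signals could not be checked. The number of arrays limits the precision.

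The table held 22690 probe sets, of which 64 control probe sets were left out. Of the other 22626, 20380 had 1 gene symbol in the platform annotation, 691 had several and 1555 had none. The gene IDs of 20351 were found in a RefSeq gene table, which changed 0 symbols. That table was used only for names, chromosomes and which genes neighbour each other. All 9 columns of values were matched to a sample by their labels.

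Signals were converted to log2(signal + 16), with no further normalization. Fold changes are on this scale, which understates the change of genes with low signals. A probe set was kept when it exceeded its array's median on at least 2 arrays, which left 12575 probe sets. A gene with several probe sets was represented by the one with the highest mean log2 signal, which gave 7487 genes. Probe sets with several symbols or none were tested only among probe sets taken one by one. A mean per group was fitted with limma 3.58.1 in R 4.3.3 (lmFit, then eBayes with trend). All 3 groups shared an estimate of the spread because 129/Sv had 2 arrays. Adjusted p-values are two-sided, from limma with Benjamini-Hochberg adjustment over all genes tested, with a threshold of 0.05. The contrasts were null against B6, null against 129/Sv, null against the unweighted mean of both strains, and B6 against 129/Sv. A gene was counted as differing from both strains when it passed against each of them in the same direction. Cyp2g1 and the probe set shared by Cyp2a4 and Cyp2a5 were also compared with exact two-sided permutation tests of 3 null against 6 wild-type arrays.

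The design, the alternatives and 28 gene lists were fixed before the data were examined. Lists were tested with camera at a preset correlation of 0.01, again with the correlation estimated per list, and with fry, adjusted over the 27 lists with at least 2 measured members. The rule for named genes took Cyp2g1, up to 14 genes higher and 14 lower against both strains, the 8 higher and 8 lower genes with the largest difference between the strains, up to 4 passing members of each list (or, where fewer than 2 passed, its 2 members with the highest mean signal), and a few enzymes and secreted proteins of this gland. Named outside this rule were Klk1b5, Klk1b11, Col3a1, Mgp, Tuba1a, Cyp2b19, Tef, Nr1d2, S100a5 and Gng13, and further genes that are said to be so. Cyp2e1 and Scgb2b24 were not among the genes tested.

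Comparisons that share control arrays share chance values. They were set beside 100 simulated draws of unchanged groups and beside the overlap expected of independent lists. These draws gave each gene independent noise and no strain difference, so they hold no variation shared across genes. In data simulated with known changes over 7487 genes, 63% of 2-fold and 91% of 4-fold changes were recovered against both strains, with 0 false calls. Against the mean of both strains the shares were 81% and 95%, with 4 false calls. Against B6 they were 78% and 95%, with 6 false calls, and against 129/Sv 63% and 91%, with 3 false calls. A simulated list shift of 0.5 was recovered with 0 other lists called. Correlations estimated within the real lists reached 0.586, far above the preset 0.01. This 1 simulated shift therefore cannot gauge how many of the real list calls are false.

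The alternatives were quantile normalization, equal array medians, pseudocounts of 1 and 64, no filter or a filter at the 75th percentile, the mean of a gene's probe sets, probe sets taken one by one, no probe sets of types that can match several transcripts, eBayes without trend, array weights, the replicate number as a block, a fit of only the groups compared, the 6 wild-type arrays as 1 group, an added 2-fold threshold, an adjusted p of 0.01, and each array left out in turn. Added after seeing the data were an olfactory marker covariate, a clock gene covariate and a fit without B6 arrays 1 and 2. The clock gene covariate was the mean of a few clock probe sets minus that of a few others. It is not the difference of the larger clock gene sets tested below. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.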

Results

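Gene expression in the lateral nasal gland was compared between Cyp2g1-null males (3 arrays) and males of both strains that contribute to their background, 129/Sv (2 arrays) and B6 (4 arrays). Cyp2g1 encodes a cytochrome P450 enzyme of the nasal mucosa. Pearson correlations between arrays, across probe sets that are not independent replicates, ran from 0.925 to 0.942, and 0 pairs of arrays were identical. The ratio of 3-prime to 5-prime signal lay between 2.59 and 2.9 for beta-actin and between 0.97 and 1.19 for Gapdh, with overlapping ranges in B6 and null arrays for both transcripts.

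The targeted gene was examined first. Its probe set (chromosome 7) had a mean signal of 594.4 ± 547.1 (SD, n = 2) in 129/Sv, 2868 ± 2201 (SD, n = 4) in B6 and 132.5 ± 73.04 (SD, n = 3) in null arrays. Signals per array were 207.5 and 981.2 in 129/Sv, 5916.8, 748.2, 2006.9 and 2799.4 in B6, and 55.7, 140.6 and 201.1 in null glands. Cyp2g1 was lower in null than in B6 arrays (log2 fold change -4.07, SE 0.618, adjusted p = 0.00221), where the null signals lie under the array medians and leave the size of the fold uncertain. Against 129/Sv the log2 fold change was -1.81 (SE 0.739, adjusted p = 0.321), which did not pass. Against the mean of both strains it was -2.94 (SE 0.584, adjusted p = 0.0282), and every null array lay below every wild-type array (exact permutation p = 0.0238). Whether the probe set lies in the deleted part of the gene is not given in the sources used here. The call against the mean was lost without 129/Sv array 2 (adjusted p = 0.107) and without null array 1, 2 or 3 (adjusted p = 0.163, 0.0938 and 0.0584). It was also lost with eBayes without trend (0.13), with the 6 wild-type arrays as 1 group (0.194) and with the replicate block (0.0656). Wild-type Cyp2g1 rose with the mean of the olfactory markers Omp, S100a5 and Gng13. Omp, the olfactory marker protein, had a signal of 3323.4 on the B6 array with the highest Cyp2g1. Its signal was 607.2 on the 129/Sv array with the lowest.

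A probe set annotated to both Cyp2a4 and Cyp2a5, neighbouring cytochrome P450 genes active on steroids and on nasal toxicants, was lower in the null arrays. It cannot tell these genes apart, and it was tested among probe sets taken one by one because it has more than 1 symbol. Its mean signal was 90683 ± 13433 (SD, n = 2) in 129/Sv, 65728 ± 21750 (SD, n = 4) in B6 and 3645 ± 1392 (SD, n = 3) in null arrays. The log2 fold change was -4.16 against B6 (SE 0.255, adjusted p = 9.66e-07) and -4.69 against 129/Sv (SE 0.304, adjusted p = 5.25e-07). Against the mean of both strains the signal was 21.5-fold lower, and the exact permutation p of 0.0119 was the smallest that 84 splits can give. B6 and 129/Sv did not differ at this probe set (log2 fold change -0.52, SE 0.289, adjusted p = 0.387). It was called against both strains in all 9 fits that left out 1 array (highest adjusted p against either strain = 3.1e-05).

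**Figure D1:**
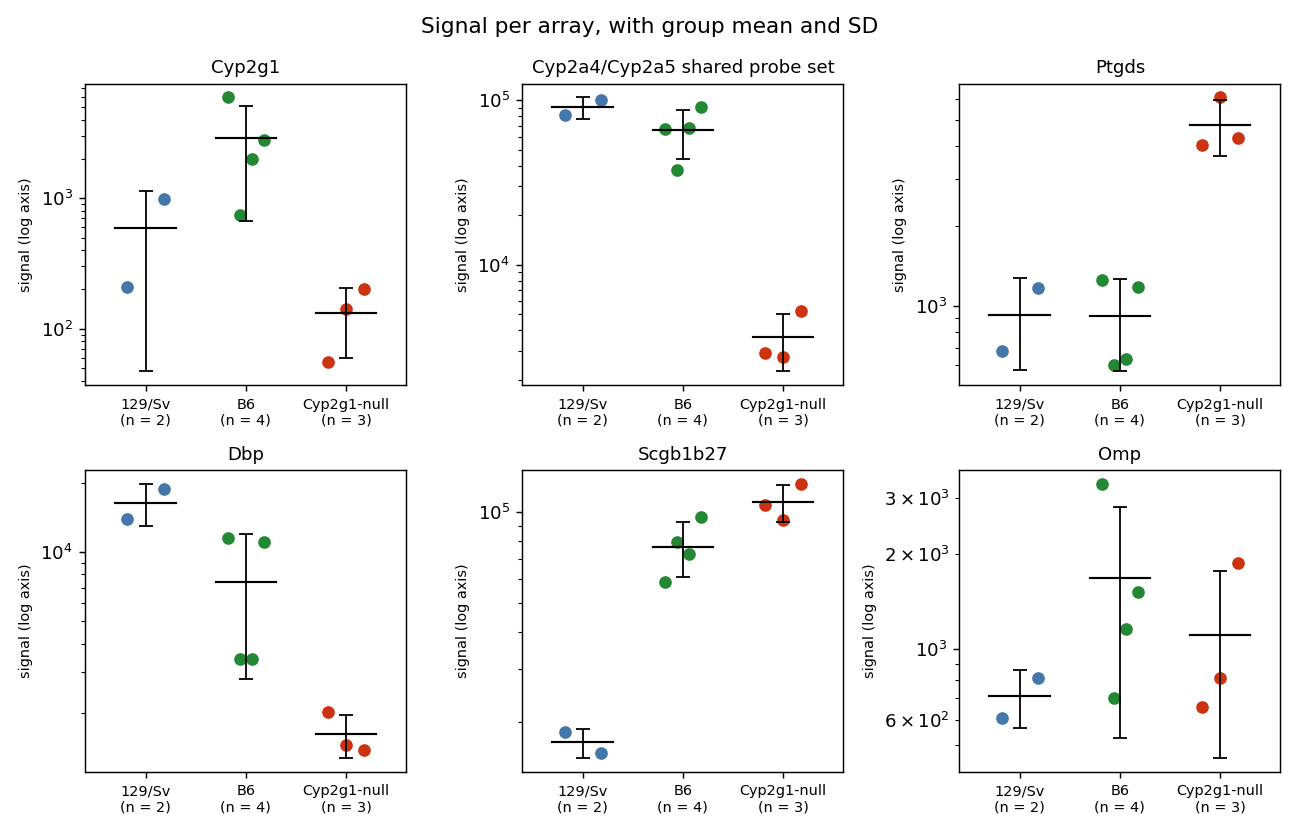
Signal per array on log axes for Cyp2g1, the probe set shared by Cyp2a4 and Cyp2a5, Ptgds, Dbp, Scgb1b27 and Omp in 129/Sv (n = 2), B6 (n = 4) and Cyp2g1-null (n = 3) pools, where points are arrays, horizontal lines are group means and bars are SD. The null arrays lie at or below 5248.9 on the shared probe set, where the lowest wild-type array is at 37580.9.

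Against both strains at once, 15 of 7487 genes passed, 9 higher and 6 lower in the null glands. Ptgds, the lipocalin-type prostaglandin D synthase, rose 5.33-fold against B6 and 5.18-fold against 129/Sv, from 919.3 ± 349.1 (SD, n = 4) and 927.8 ± 349.9 (SD, n = 2) to 4783 ± 1117 (SD, n = 3), with adjusted p-values of 0.000224 and 0.000969. Sphk1, a sphingosine kinase, rose with log2 fold changes of 1.36 and 2.41 (adjusted p = 0.0134 and 0.000965). Ccn1, an immediate early matricellular gene, rose 3.31-fold and 2.28-fold (adjusted p = 0.00129 and 0.0493). Rps27, a ribosomal protein, rose 1.79-fold and 3-fold. Smaller rises, with log2 fold changes between 0.447 and 0.807 against either strain, were found for Gp2, a secretory granule membrane glycoprotein, Ccl28, a mucosal chemokine, Ramp1, a subunit of the CGRP receptor, Rell1 and Dusp14. Dbp, a transcription factor with circadian expression, fell 3.9-fold against B6 and 10.1-fold against 129/Sv (adjusted p = 0.0121 and 0.000969). Adh1, a class I alcohol dehydrogenase, fell 2.7-fold and 1.73-fold (adjusted p = 6.75e-05 and 0.0177). Kcnn4, a calcium-activated potassium channel, Fam3c, Gng10 and Marchf7 also fell, with log2 fold changes between -0.936 and -0.38. A second Marchf7 probe set did not show the change (-0.05 against the mean of both strains).

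Of these 15 genes, Ptgds was the 1 called in all 9 fits that left out an array. The count moved to 9 and 4 without 129/Sv array 1 or 2, to 31 and 6 without B6 array 1 or 3, and to 3, 4 and 7 without null array 1, 2 or 3. Simulated unchanged groups gave at most 0 such genes, and independent lists of these sizes would share 1.54 higher and 0.81 lower genes. The simulated genes varied independently and had no strain difference, so their count cannot gauge overlap among genes that vary together. Part of any overlap may come from the null arrays, which both comparisons share and which are too few to split. The fold changes against the 2 strains correlated at 0.235 across genes, which are not independent replicates (0.475 in simulated unchanged groups), with a covariance of 0.03 (0.027 simulated). With equal array medians 15 genes passed, 5 higher and 10 lower, of which 11 were among the 15 above.

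**Figure D2:**
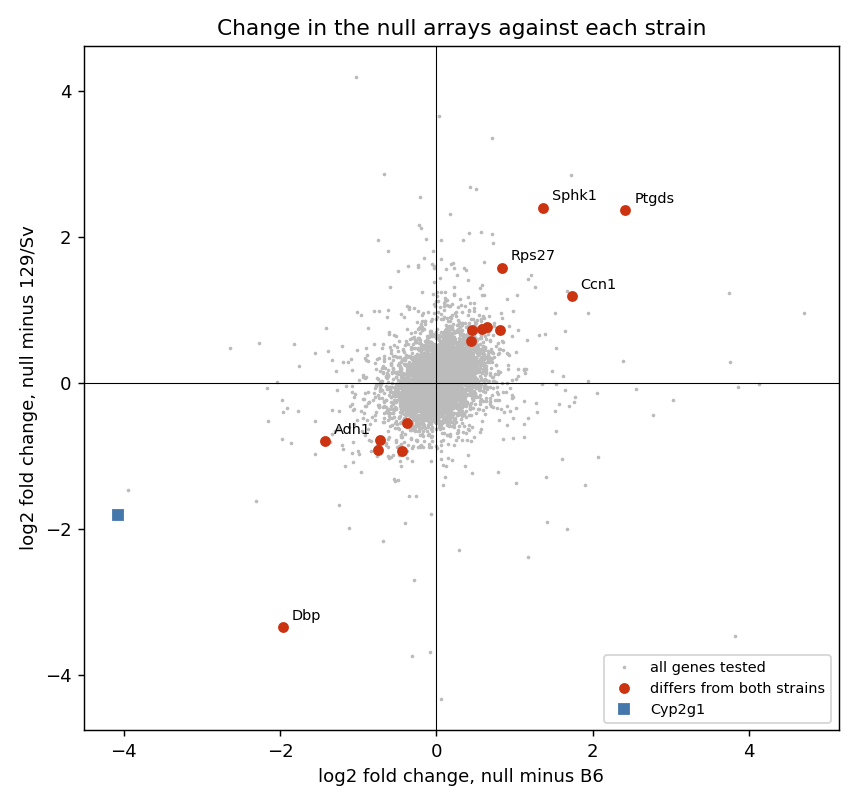
Log2 fold change of each of 7487 genes in null against B6 (horizontal axis) and against 129/Sv (vertical axis), with red points for the 15 genes that passed against both and a square for Cyp2g1. Ptgds lies near 2.4 on both axes, while most genes far from 0 on one axis lie near 0 on the other.

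The contrast against the mean of both strains called 96 genes, 59 higher and 37 lower, of which 23 changed at least 2-fold. It also takes in genes on which the strains differ. Pttg1, the securin gene, rose 3.61-fold in this contrast, yet its signal was 9946 in null and 9747 in B6 arrays and 774.7 in 129/Sv arrays. Cap1, an actin-binding protein, fell by 1.89 on the log2 scale through the same strain difference. The count was 38 without 129/Sv array 2, 196 without B6 array 1, and 30, 32 and 38 without null array 1, 2 or 3. It was 2 when all 6 wild-type arrays were fitted as 1 group, which adds the strain difference to the spread. With equal array medians 95 genes passed, 47 higher and 48 lower.

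The secreted androgen-binding proteins were higher than the mean of both strains as a group. All 3 measured secretoglobins passed (3 of 3 also adjusted over the list alone; camera adjusted p = 2.29e-09; adjusted p = 0.0253 with an estimated correlation). Scgb1b27 had a mean signal of 17040 ± 1926 (SD, n = 2) in 129/Sv, 76800 ± 15790 (SD, n = 4) in B6 and 108200 ± 15230 (SD, n = 3) in null arrays. Scgb2b27 followed the same order with 21270, 55040 and 88340, and Scgb1b2 with 751.3, 3288 and 3716. All 3 were also higher in B6 than in 129/Sv (camera adjusted p = 2.03e-07; adjusted p = 0.0437 with an estimated correlation). Against B6 alone the list passed with a camera adjusted p of 0.0313 (adjusted p = 0.32 with an estimated correlation; 0.141 without B6 arrays 1 and 2), and no member passed over all genes, with adjusted p-values of 0.0797 for Scgb1b27, 0.0667 for Scgb2b27 and 0.703 for Scgb1b2. Obp1a, an abundant odorant-binding protein, had signals of 129500, 143900 and 128800 in 129/Sv, B6 and null arrays (adjusted p = 0.75 against the mean).

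Markers of ciliated and respiratory epithelium, a neighbouring tissue, were higher in null glands. All 10 measured members had positive changes, 3 passed over all genes (Dnah5, Lrrc23 and Tppp3) and 10 passed adjusted over the list alone (median log2 fold change 0.47, camera adjusted p = 2.29e-09; adjusted p = 0.0273 with an estimated correlation). Dnah5, an axonemal dynein, was 1.55-fold higher than the mean of both strains (SE 0.13 on the log2 scale, adjusted p = 0.0319), and Lrrc23, a radial spoke protein, was 1.55-fold higher (SE 0.126, adjusted p = 0.0275). Against B6 the list passed with a camera adjusted p of 1.05e-07 (adjusted p = 0.0818 with an estimated correlation), and against 129/Sv with 7.84e-06 (adjusted p = 0.0961 with an estimated correlation). Tuba1a, a member of this list, is expressed in many cell types.

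Of 17 measured immediate early and handling-induced genes, all had positive changes against the mean of both strains. Over all genes 3 passed, Ccn1, Jun and Btg2, and 6 passed adjusted over the list alone (camera adjusted p = 7.74e-06). The list lost its call with an estimated correlation (adjusted p = 0.485). Over 25 other settings, that one included, its median ran from 0.158 to 0.415 and 2 lost the call. With the preset correlation it was also called against B6 (camera adjusted p = 0.000128) and against 129/Sv (camera adjusted p = 0.000907). With an estimated correlation these adjusted p-values were 0.625 and 0.843. Null array 2 stood above all other arrays for Fos, at 8513.1 against 417.7 to 1228.8, and for Egr1, at 9407 against 973.2 to 1839.1; both were chosen after their values were seen.

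Other lists were called against the mean of both strains only with the preset correlation. Cyp2 genes of the chromosome 7 cluster had a median log2 fold change of -0.41 (camera adjusted p = 0.00696; adjusted p = 0.445 with an estimated correlation). Of its 4 measured members 0 passed over all genes and 2 passed adjusted over the list alone. Cyp2f2, the most abundant of them, had signals of 73730, 70960 and 53220 in 129/Sv, B6 and null arrays (adjusted p = 0.057), and it passed in 10 of 26 other settings. Cyp2b10 had 7942, 6311 and 5148 (-0.44 against the mean, adjusted p = 0.199). Its other probe sets gave -0.59 and -1.08 against the mean, and it passed in 1 of 26 other settings, without probe sets that can match several transcripts. Interferon-stimulated genes had positive changes in 15 of 16 members, none of which passed over all genes and 1 of which passed over the list alone (camera adjusted p = 0.0024; adjusted p = 0.445 with an estimated correlation). That list was also higher in B6 than in 129/Sv (camera adjusted p = 0.000407; adjusted p = 0.294 with an estimated correlation). Androgen-responsive salivary genes (7 of 8 positive), major histocompatibility genes (12 of 14 positive) and cartilage and bone markers (2 of 8 positive) each had a camera adjusted p of 0.0443. With an estimated correlation the adjusted p was 0.445 for the androgen-responsive genes, 0.485 for the histocompatibility genes and 0.445 for the cartilage markers. Adjusted over the list alone, 1 of each of these lists passed. The androgen-responsive genes lost their call without 129/Sv array 1 or 2 (adjusted p = 0.0612 and 0.0659) and without null array 2 or 3 (0.0619 and 0.357). The histocompatibility genes lost it without 129/Sv array 1 or 2 (0.0512 and 0.122), B6 array 2 (0.0664) and null array 2 or 3 (0.209 and 0.124). The cartilage markers lost it without 129/Sv array 1 or 2 (0.0512 and 0.0898), B6 array 1 (0.0777) and null array 1 or 2 (0.141 and 0.362).

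No shift was called in the remaining lists. Their median log2 fold changes against the mean of both strains were 0.05 for other genes beside the Cyp2 cluster, -0.04 for phase 1 xenobiotic enzymes, 0.07 for phase 2 enzymes and transporters and -0.05 for steroid and androgen metabolism. The medians were -0.07 for lipocalins and odorant-binding proteins, 0.03 for exocrine secretory proteins, 0 for NRF2 targets, -0.04 for endoplasmic reticulum stress genes, 0.06 for cholesterol and fatty acid synthesis and 0.03 for cell cycle genes. For cell type markers they were 0.03 for B and plasma cells, -0.03 for macrophages and neutrophils, -0.01 for olfactory neurons, 0.08 for basal and duct cells and 0.18 for skeletal muscle. They were 0.11 for adipocytes, 0.15 for erythroid cells, -0.08 for endothelium and stroma and 0.08 for nerve. Some of these lists had few measured members. There were 2 each for skeletal muscle and erythroid cells, 4 for adipocytes, 5 each for B cells and nerve and 6 for olfactory neurons. Medians over so few genes say little about those cell types. The olfactory value lies between opposite medians, -0.624 against B6 and 0.419 against 129/Sv, with 1.129 for B6 minus 129/Sv. None of these was called (camera adjusted p = 0.21, 0.496 and 0.0757). Of 17 T cell and natural killer cell markers, 14 were on the array and 0 passed the signal filter. Median and mean differed in sign for other genes beside the cluster (mean -0.003), lipocalins (mean 0.282) and olfactory neuron markers (mean 0.015), and camera ranked olfactory neuron markers, NRF2 targets and B cell markers downward and macrophage markers upward, against the sign of their means. Single members that passed included Gsto1, a detoxifying enzyme, and Reg3g, an antibacterial lectin, which were higher than the mean of both strains but did not pass against B6 (adjusted p = 0.338 and 0.139). Agr2, Lcn3 and Pdia6 were lower than the mean but did not pass against 129/Sv (adjusted p = 0.497, 0.21 and 0.844). Aldh2 passed through the strain difference alone, with signals of 18390 in null and 18510 in B6 arrays, and its other probe sets did not rise (-0.34 and -0.01 against the mean).

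**Figure D3:**
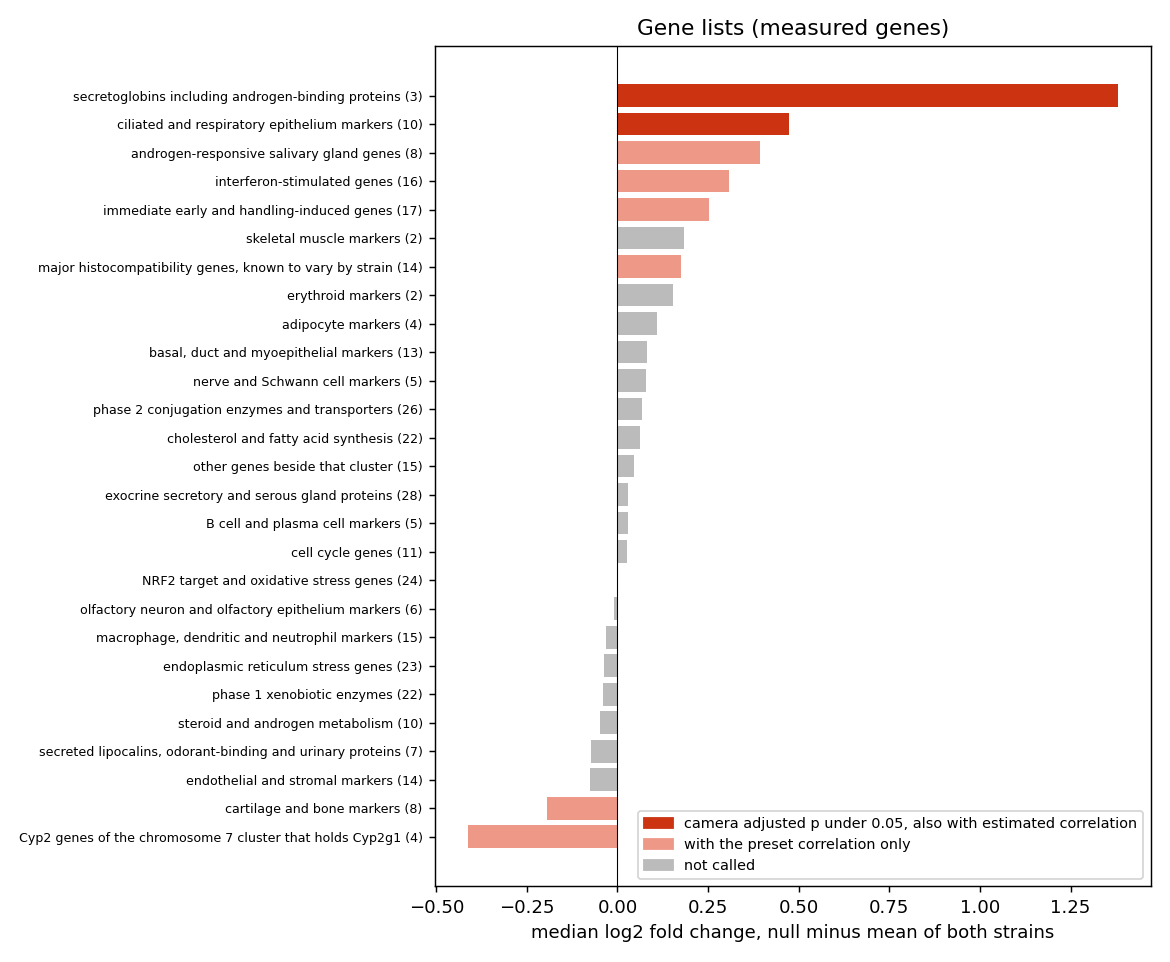
Median log2 fold change of each gene list in null arrays against the mean of both strains, with the number of measured genes in parentheses. The secretoglobins (1.38) and ciliated markers (0.47) are the lists called with both the preset and the estimated correlation.

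Null and B6 arrays differed at 213 genes, 107 higher and 106 lower, and null and 129/Sv arrays at 165, 108 higher and 57 lower. Slc14a1, a urea transporter, and Serpina3n, a serine protease inhibitor, were higher in null than in B6 arrays (adjusted p = 0.000224 each), with signals in null arrays like those in 129/Sv (2401 and 2407 for Slc14a1, 2732 and 2787 for Serpina3n). Androgen-responsive salivary genes were higher in null than in B6 arrays as a list, with 3 of 8 members called, the kallikreins Klk1, Klk1b5 and Klk1b11 (camera adjusted p = 0.000421; adjusted p = 0.292 with an estimated correlation). Klk1 was lower on B6 arrays 1 and 2 than on B6 arrays 3 and 4; without the first pair the list kept its call (camera adjusted p = 0.000613) and Klk1 did not (adjusted p = 0.0928). Against B6, major histocompatibility genes were also higher (camera adjusted p = 0.00471; adjusted p = 0.35 with an estimated correlation), and cartilage markers (0.0052; 0.32) and endothelial and stromal markers (0.00169; 0.38) were lower. Against 129/Sv, interferon-stimulated genes were higher (camera adjusted p = 6.19e-06; adjusted p = 0.126 with an estimated correlation) and Cyp2 genes of the cluster lower (0.0022; 0.375). None of these lists was called against the other strain. Against 129/Sv the camera adjusted p was 0.839 for androgen-responsive genes and 0.837 for both histocompatibility genes and cartilage markers. For endothelial and stromal markers it was 0.878. Against B6 it was 0.817 for interferon-stimulated genes and 0.365 for the Cyp2 genes. The 213 became 472 without B6 array 1 and 111, 110 and 101 without null array 1, 2 or 3. The 165 became 108 and 65 without 129/Sv array 1 or 2 and 74, 88 and 96 without null array 1, 2 or 3. With equal array medians the 129/Sv comparison had 86 higher and 76 lower genes.

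The strains themselves differed at 407 genes, 218 higher in B6 and 189 higher in 129/Sv. Among named genes, Rpgrip1, Pttg1, Rab6b, Trim34a, Ghitm, Sftpc, Naip2 and Sult1d1 were higher in B6, with 12.4-fold for Pttg1 (adjusted p = 1.38e-09). Rpgrip1 had signals of 158.2 and 29 in 129/Sv, under the array medians, and a mean of 3298 in B6 (adjusted p = 1.25e-06). Slc14a1, Serpina3n, Kcnab1, Cap1, Tmem87a, Mucl2, Gch1 and Sdc4 were higher in 129/Sv, with 9.86-fold for Sdc4. Second probe sets of Sdc4 and Trim34a went the other way, at log2 fold changes of 1.44 and -1.93 for B6 minus 129/Sv, and a second Ghitm probe set gave 0.45 in place of 2.76. Of 8 measured androgen-responsive salivary genes 5 were lower in B6 (camera adjusted p = 0.00235; adjusted p = 0.294 with an estimated correlation). The median of this list ran from -1.62 to -0.23 over 25 settings, of which 3 lost the call. Klk1 had signals of 40768.1 and 40802.6 on B6 arrays 1 and 2 and of 58537.5 and 61402.1 on B6 arrays 3 and 4. Endothelial and stromal markers were higher in B6, with 2 of 14 called, Col3a1 and Mgp (camera adjusted p = 0.00821; adjusted p = 0.53 with an estimated correlation), a call lost without B6 array 1 (adjusted p = 0.0557). The gene count was 201 and 209 without 129/Sv array 1 or 2, where the lone array is assumed to vary like the other groups.

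Many of the differences between null glands and a single strain lay where the strains also differed. Of the 407 strain genes, the null arrays differed from B6 alone, on the 129/Sv side, at 115, from 129/Sv alone, on the B6 side, at 105, from both at 11 and from neither at 176. Of the 213 genes between null and B6, 125 were shared in direction with 129/Sv against B6, where independent lists would share 5.79. Simulated unchanged groups shared at most 1, but their genes varied independently, so that value cannot gauge this overlap. With the B6 arrays split between the comparisons, 57 to 78 of 95 to 244 were shared over 6 splits, which is 31.8% to 62.6%. Of the 165 genes between null and 129/Sv, 115 were shared with B6 against 129/Sv, where independent lists would share 4.58, and part of this excess may come from the shared 129/Sv arrays, which are too few to split.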

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

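All explanations in this part were tested only after the results were seen, except the counts of other splits of the arrays, which were planned; the check of splits that keep the null arrays was added afterwards.

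In the 4 B6 arrays, 89 values (the named genes and the shared probe set) were checked for an array far from the others, and chance alone marks about 1 in 20. There were 5 such values. Agr2 was low on B6 array 1 (4279.7 against 5622.5 to 5894; gap over range 0.853), and Scd2 was low on the same array (10798.5 against 14261.8 to 14547.2; 0.933). Asns was high on B6 array 2 (51499.8 against 41845.3 to 42405.5; 0.936). Btg2 and Xbp1 were low on B6 array 4 (3567.2 for Btg2, with a gap of 0.89, and 72693.8 for Xbp1, with a gap of 0.848).

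A probe set with no gene name here lay outside the gene comparisons. Its signal was 82.3 and 81.2 in 129/Sv, 8493.1 to 12168.3 in B6 and 17340.7 to 19582.7 in null arrays. It was above B6 by 0.88 on the log2 scale (adjusted p = 0.0012) and above 129/Sv by 7.53 (adjusted p = 4.13e-13). The 129/Sv signals lie under the array medians, which leaves the size of the second difference uncertain.

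The low signal of the probe set shared by Cyp2a4 and Cyp2a5 is the first pattern weighed. A strain variant under the probe set is argued against, since the lowest wild-type array was 7.16 times the highest null array and 129/Sv was 1.38 times B6. Cross-hybridisation of Cyp2g1 transcript is argued against by 129/Sv array 1, which had the least Cyp2g1 among wild-type arrays and a shared signal 15.5 times the highest null array. The trend on Dbp over the 6 wild-type arrays (slope 0.374, SE 0.146), carried beyond their range, gives 20.9% of the fall, or 37.2% with the slope plus 2 standard errors, while a clock gene covariate that itself differs between the groups left -3.39 (SE 0.412) in place of -4.42 (SE 0.241) against the mean. With it the call against B6 held at -3.66 (SE 0.27). The call against 129/Sv was lost at -3.11 (SE 0.604, adjusted p = 0.114), where the fold fell from -4.69 and the SE rose from 0.304. The covariate holds only a few clock probe sets picked after the data were seen, so the lost call decides nothing about the clock. Loss of the Cyp2g1 enzyme and altered regulation of its neighbours by the targeted allele cannot be told apart with 1 allele and no rescue. The measured Cyp2 genes of the cluster had a median log2 fold change of -0.41 against the mean of both strains. Against B6 the median was -0.185, and the list was not called (camera adjusted p = 0.365). A member, Cyp2b19, also differed between the strains (-1.503 for B6 minus 129/Sv, adjusted p = 0.00042).

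Lower Dbp in the null arrays is the second pattern. The lowest wild-type Dbp signal was 1.7 times the highest null signal, so the null arrays did not lie between both strains. Dbp was taken up because it passed as lower against both strains on these same arrays. The ratio is therefore no separate test of a strain difference. Whether a mixed background can lie outside both strains was not tested. Of 8 other clock output genes 7 had negative and of 5 genes of the opposite phase 4 had positive changes against the mean of both strains, and the difference of these sets was -1.08 in null against wild-type arrays (exact permutation p = 0.0476, over 84 splits), though only 2 of these 13 genes passed, Tef and Nr1d2. The difference was -0.71 against B6 alone (exact permutation p = 0.143, over 35 splits) and -1.82 against 129/Sv, and B6 minus 129/Sv was -1.10, so the pooled value also holds a strain difference, and the lowest wild-type value (-0.24) lay within the null range (up to -0.238). Another clock phase at collection, whose times were not used here, and a change of the clock by genotype therefore stay open.

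The wide spread of Cyp2g1 among wild-type arrays is the third pattern. Over the 6 arrays Cyp2g1 rose with the mean of Omp, S100a5 and Gng13, with Spearman's rho of 0.943 (permutation p = 0.0167, adjusted 0.0334 over 2 relations computed) and Pearson's r of 0.967 (permutation p = 0.00417, adjusted 0.00834). The olfactory list had 6 measured members, and no relation with its other members was computed. Without the 2 arrays farthest from the median r was 0.973. Within B6, Cyp2g1 and the marker mean had the same order from low to high (arrays 2, 3, 4 and 1), but no test was run within a strain. Olfactory epithelium RNA in the dissected pools, where Cyp2g1 is known to be expressed, is a candidate source of the wild-type signal. Null array 3 had an Omp signal of 1869.7 with a Cyp2g1 signal of 201.1, and with the olfactory marker covariate Cyp2g1 was also called lower than in 129/Sv (-2.8, adjusted p = 0.0302); biological differences between the strains stay open.

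The planned splits of the arrays give the chance of the counts. Of 100 splits of the 9 arrays, drawn from 1260, the real one alone gave as many as 15 genes against both strains (highest of the others 1) and it alone gave as many as 96 against the mean (highest of the others 91), which is 1 of 100 each. However, 2 drawn splits that kept the 3 null arrays and reassigned wild-type arrays between the strains gave 3 and 1 genes against the mean and 0 and 1 against both. Mixing the strains thus lowers the counts by itself, and these splits do not decide whether chance can be excluded. Between null and B6, 2 of 35 splits gave as many as 213, so chance cannot be excluded from that count alone. The other split, with 250 genes, set B6 arrays 2, 3 and 4 apart from B6 array 1 and the 3 null arrays, and the split with 91 genes had the same 3 arrays in the null place, which points to a structure that involves B6 array 1.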

How the results depend on the processing

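The covariates and the fit without B6 arrays 1 and 2 were chosen after seeing the data. Counts are given in the order null against the mean, null against B6, null against 129/Sv, B6 against 129/Sv and against both strains (96, 213, 165, 407 and 15), where a count moved by over 1.5 times. Without trend 35, 115, 93 and, against both, 4 genes passed, with 5 lists in place of 8 and Cyp2g1 at -2.94 (adjusted p = 0.13). Of those 4 genes only 1, Ptgds, was among the 15. The mean of a gene's probe sets gave 13 genes against both, 9 of them among the 15. Array weights gave 191 and 364, and 28 against both. Probe sets one by one gave 154 against the mean, 256 against 129/Sv and 653 between strains, by testing 12575 in place of 7487. No filter gave 7 against both, and the stricter filter 5 lists, as did leaving out probe sets that can match several transcripts. With an added 2-fold threshold 23, 65, 68, 145 and 4 passed, and at adjusted p 0.01 28, 83, 65, 202 and 2, with 5 lists and Cyp2g1 (-2.94, adjusted p = 0.0282) no longer called, as stricter thresholds must. All 6 wild-type arrays as 1 group gave 2 genes and Cyp2g1 at -3.31 (adjusted p = 0.194), since the strain difference enters the spread. Estimated correlations and fry each left 2 lists. With the olfactory marker covariate 201 genes differed between strains and 8 from both. The clock gene covariate gave 8, 49, 4, 40 and 0 genes and 10 lists, Cyp2g1 at -1.16 (adjusted p = 0.997) and the shared Cyp2a4 and Cyp2a5 probe set at -3.39 (adjusted p = 0.114 against 129/Sv); it differs between the groups. Under it medians of opposite sign were called for phase 1 enzymes (0.25; 0.18 for B6 minus 129/Sv), NRF2 targets for B6 minus 129/Sv (0.24), B and plasma cells (-0.48), olfactory markers (1.22) and phase 2 enzymes for B6 minus 129/Sv (0.42). Without B6 arrays 1 and 2 the counts were 254, 397, 254 and, against both, 39. Except where said, the cause was not tested.

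Leaving out 1 array gave 30 to 196, 101 to 472, 65 to 202, 201 to 559 and 3 to 31 genes, 5 to 8 lists, Cyp2g1 between -3.48 and -2.40 and the shared probe set between -4.72 and -4.26, called each time. The replicate numbers did not visibly pair the null and B6 arrays. With the group means removed, same-numbered null and B6 arrays correlated at 0.011, -0.009 and -0.002. On this measure 129/Sv array 1 and B6 array 1 gave 0.104, and the differently numbered 129/Sv array 2 and B6 array 4 gave 0.126. With the replicate block 83, 155, 161, 330 and 16 genes and 7 lists passed, and Cyp2g1 was -2.96 (adjusted p = 0.0656). Other results kept their side of the threshold in 1947 of the named-gene comparisons and 1287 of those of lists. These include genes and lists not called in the main fit. A call was lost in 336 and 53 comparisons and gained in 12 and 21. Of the 15 genes against both strains, Dusp14 lost its call in 19 of 26 settings. Ccl28, Ccn1, Fam3c, Kcnn4 and Marchf7 each lost it in 17, Dbp, Gp2 and Sphk1 in 5 and Ptgds in 1, and the rest in 8 to 16. The sign changed in 65 named-gene comparisons, 0 of them called in either fit, which include Cyp2g1 against 129/Sv with the clock gene covariate (-1.81 to 0.89, adjusted p = 1), and in 101 list comparisons, 6 of them called. Detection calls were not used here, so the limit they set on low genes is unknown.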

Other observations

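All tests in this part were chosen after the results were seen.

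Several secreted proteins differed by large factors within B6, and their values were chosen after they were seen. Mup5, a major urinary protein, had signals of 26292.2, 29517.9, 159511.2 and 142899 on B6 arrays 1 to 4, against 113838.9 to 136961.9 in 129/Sv and 115371.6 to 145205.9 in null arrays. For 2310057J18Rik the B6 signals were 607.3, 958.4, 49675.4 and 45604.4. Car6, a secreted carbonic anhydrase, had 387.5, 593.7, 8017.5 and 7400.6, and Wfdc12, a protease inhibitor, had 530.2, 631.2, 8125.5 and 15125.5. In 129/Sv, Car6 was 10385.4 and 66481.3.

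B6 array 1 stood apart from the other B6 arrays. On the first principal component it lay with them (13.4 against 15.1 to 19.1, with null arrays at -8.2 to -7.4), and on the third it lay apart from all other arrays (22.6 against at most 8.5). Over the 472 genes called between null and B6 without it, its median position was 0.49 on a scale from 0 (the other B6 arrays) to 1 (the null arrays), and 49.8% of those genes were nearer to null. The same measure, each over the genes called without the array in question (160, 144 and 147), gave 0.08, 0.06 and -0.01 for B6 arrays 2, 3 and 4. Its Cyp2g1 signal, 5916.8, was the highest of all 9 arrays, and its shared Cyp2a4 and Cyp2a5 signal was 66850.9.

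A segment of 129/Sv chromosome around the targeted gene may be carried by the null line. Among the 150 measured genes nearest to Cyp2g1 on chromosome 7, null arrays were on the 129/Sv side at 8 strain genes and on the B6 side at 5, against 107 and 100 elsewhere (Fisher's exact two-sided p = 0.575). The genes near Cyp2g1 are too few to decide, so the segment stays open.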
